A study of Mus musculus with 18 samples.

How the data were processed

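Total RNA of 18 mouse hearts was sequenced, 1 library per animal, with a commercial column kit for extraction and a universal RNA library kit, per the labels. The hearts were taken at day 7 in 3 groups of 6 animals: sham surgery (SHAM), ischemia-reperfusion (IR), and ischemia-reperfusion with decursin (IR+Decursin). Groups and replicate numbers came from the labels, and each group's libraries are separate animals. The labels also name 3 batches, each holding 1 group, so the batch and the group cannot be told apart and no batch term can be fitted. The dose and route of decursin and the details of the surgery are not given in the sources used here.

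The authors deposited raw read counts per gene symbol for 25731 symbols and 18 libraries. Per the submitters' processing notes, reads were trimmed with fastp, aligned with HISAT2 to the mouse build GRCm39 and counted with HTSeq. Versions, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so genes with near-identical copies or with antisense or overlapping neighbours are uncertain. The FPKM values deposited for the same symbols are the counts scaled to gene length in kilobases and to the library total. They equal that formula for 347198 values above 0, with a largest relative deviation of 1.58e-09. FPKM values therefore carry no correction for the make-up of a library beyond its total. The reference annotation at hand is of an older build, so it served only for names: 24465 of the 25731 symbols (95.1%) matched a RefSeq symbol or synonym, and no coordinates are given.

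Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by group, which left 15088 for testing, and libraries were scaled by TMM factors. All 18 libraries entered 1 quasi-likelihood fit with a mean per group and robust dispersion, leaving 15 residual degrees of freedom. Each of the 3 comparisons was tested with a two-sided quasi-likelihood F-test and Benjamini-Hochberg adjustment, and genes at a false discovery rate under 0.05 were called. Levels are counts scaled to a library of 1 M counts (CPM, with TMM factors) as mean ± SD over 6 libraries, and changes are log2 fold changes ± standard error (SE). At the depth of 27.5 to 35.0 M counts, 3 counts over a group of 6 libraries was taken as the floor for a gene at 0. Floors and the 95% intervals of count ratios cover counting error only.

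The lists of pathways and cell type markers, the tests and the rule for the genes named were fixed before the data were examined. Of 51 lists, 50 held at least 3 tested genes. The lung and airway epithelium list held 0 tested genes and was left out. Lists were tested with fry in limma 3.58.1, two-sided, which asks whether the genes of a list move on balance in one direction and does not compare the list with other genes. Its either-direction form asks whether the members move at all. Adjustment was over the 50 lists of a comparison at 0.05. The same lists were tested with camera, which does compare a list with the other genes, using an inter-gene correlation estimated per list. Members were counted over all genes tested and adjusted over the list alone. For 25 of the lists (cell types, ferroptosis, heme and iron) the mean log2(CPM + 1) of the members was taken per library and compared with a two-sided exact permutation test over 924 splits, whose smallest possible p is 0.00216. Per comparison, the genes named are those called with a mean of at least 2 CPM in the higher group that had the 8 largest rises and the 8 largest falls (4 and 4 for IR+Decursin against SHAM), without models named by Gm, Rik, Ensembl, clone or pseudogene symbols and without immunoglobulin or T cell receptor segments. Where no gene was called, the 5 higher and 5 lower genes with the smallest p were taken. A panel of 16 ferroptosis, iron, cardiac and matrix genes and up to 4 members of each list with the smallest adjusted p were added.

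The part of the IR change that remained in IR+Decursin was measured with an index per library. Genes called in 3 IR and 3 SHAM libraries, 4824 in one part and 3826 in the mirror part, gave the IR change, and the index is the slope of another library's log2 deviations from the held-out SHAM libraries on that change. The mean of the SHAM libraries is 0 by construction, and single SHAM libraries are not held there. Comparisons that share the IR or the SHAM libraries were set beside simulated groups with no effect and beside splits of the shared libraries.

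The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts, a filter of 1 CPM in 6 libraries, fits of the compared groups alone, limma with voom and quality weights, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) and for genes with a mean of at least 1 FPKM, scaling without the mitochondrial and haemoglobin genes, the replicate number as a block, and leaving out each library in turn. A term for the libraries with over 1000 Xist counts, leaving those libraries out, leaving out those with over 0.5% of counts in Gm26917, leaving out single libraries from the index, and total-count scaling for the medians of all genes and of lists were chosen after seeing the data. On data simulated from the libraries' means and sizes, the fit called 72.0% of genes changed 2-fold and 92.9% of those changed 4-fold for IR against SHAM, over 14919 genes. The shares were 80.6% and 96.9% for IR+Decursin against IR, over 14957 genes, and 75.8% and 94.0% for IR+Decursin against SHAM, over 14922 genes. Of the genes called there, 3.55%, 2.79% and 5.06% had not been changed. In these draws genes varied independently and had the same mean in all groups apart from the changes set. Differences between animals that move many genes together were absent, so these shares may not hold for the real comparisons. The index recovered 101%, 49.1% and 0.436% of simulated changes of 100%, 50% and 0%, over 15088 genes. Between libraries of a group, the chi-square per degree of freedom of the counts was 15.4 to 346, so no library was a copy of another.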

Results

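Heart transcriptomes of 18 mice were compared at day 7 after sham surgery (SHAM), ischemia-reperfusion (IR), or ischemia-reperfusion with decursin, a pyranocoumarin of Angelica gigas root (IR+Decursin), with 6 animals per group. Libraries held 32.2 ± 1.96 M counts (mean ± SD) and 18435 to 20389 genes with counts. The 13 mitochondrial genes took 31.1 ± 1.56% of counts in SHAM, 24.4 ± 3.06% in IR and 24.6 ± 2.21% in IR+Decursin. On the first principal component (53.0% of variance) SHAM lay at -66.3 to -56.7 and IR lay on the other side, up to 67.3. IR+Decursin spread from -47.9 to 54.3. Xist, transcribed from the inactive X chromosome of females, had 14232 counts in IR 3, 14072 in IR 4 and 14219 in IR+Decursin 2, for at most 8 in the other 15 libraries. The Y-linked helicase gene Ddx3y had 0 in these 3, although the labels give all animals as male and wild type. The gene model Gm26917 had 2332306 counts in IR+Decursin 6 (7.54% of that library), 308832 in IR 1 (0.915%) and 16030 to 55028 in the other 16 libraries. The source of these reads was not tested. Each batch named in the labels holds a single group, so the batch and the group cannot be told apart in any comparison below.

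**Figure D1:**
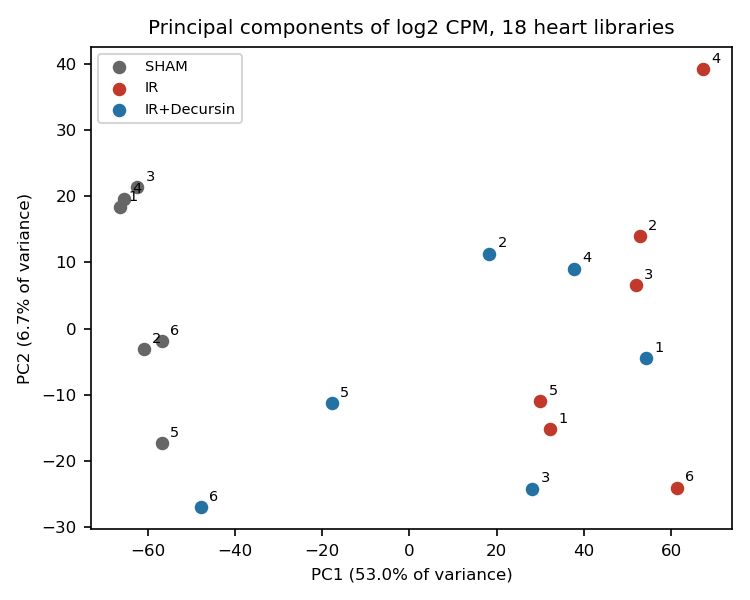
Libraries on the first and second principal component of log2 CPM (percent of variance on each axis), 1 point per animal, coloured by group. IR+Decursin 5 and 6 lie toward SHAM and the other IR+Decursin libraries among or near IR.

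In IR hearts, genes of scar matrix and of immune cells rose, and genes of cardiomyocyte contraction and energy supply fell. The collagen gene Col1a1 rose from 110 ± 16.1 to 2186 ± 309 CPM (log2 fold change 4.31 ± 0.59 SE, adjusted p = 3.11e-05, every IR library above every SHAM library, 6 of 6). Timp1, which encodes an inhibitor of matrix proteases, rose from 3.17 ± 0.924 to 116 ± 37.3 CPM (5.20 ± 0.57, adjusted p = 7.13e-06, 6 of 6). The fetal myosin heavy chain gene Myh7 rose (3.71 ± 0.56, adjusted p = 6.44e-05) and the adult form Myh6 fell (-0.65 ± 0.15, adjusted p = 0.00162), each in 6 of 6 libraries. In all, 3810 genes rose and 3269 fell of 15088 tested (46.9% changed, 53.8% of them upward). Of these, 1742 and 272 did so at least 2-fold. The median of all genes was -0.00 with TMM factors and 0.31 with total-count scaling. The deposited FPKM carry no such factors, and limma-trend on them gave 6901 up and 1089 down with a median of 0.17 (6940 and 1092 with a median of 0.27 for a pseudocount of 0.1, 5393 and 978 with a median of 0.22 for genes at 1 FPKM or more).

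Among genes that met the naming rule with its minimum of 2 CPM, Serpinb2, Esr1, Saa3, Arg1, Sprr1a, Cd5l, Il6 and Cemip had the largest rises. Saa3 is an acute-phase apolipoprotein (9.91 ± 1.78, adjusted p = 0.000327), Arg1 the arginase of wound macrophages (9.78 ± 1.48, adjusted p = 8.16e-05), and Sprr1a a stress-induced cornified envelope gene (8.31 ± 1.12, adjusted p = 2.88e-05). Cd5l is secreted by macrophages (8.10 ± 1.55, adjusted p = 0.000514), and Cemip degrades hyaluronan (7.24 ± 1.40, adjusted p = 0.000514). All of these rose in 6 of 6 libraries. Folds that moved over 1.5 times with 1 library left out were Cd5l at 6.98 without IR 2, Saa3 at 10.53 without SHAM 3, and Sprr1a at 8.91 without SHAM 6 and 7.72 without IR 6. With voom and quality weights Saa3 was 9.57 and was not called (adjusted p = 0.159). The cytokine gene Il6 had 531 counts in IR and 1 in SHAM, a ratio of 513 (95% interval 91.7 to 20295), and without SHAM 2 it had 0 in SHAM. Serpinb2, an inhibitor of plasminogen activators, had 0 counts in SHAM and stood at least 298-fold above a floor of 3 counts in IR (5.37 ± 5.89 CPM), or 175-fold without IR 2 (3.14 CPM). Esr1, the estrogen receptor gene, rose (10.22 ± 3.49, adjusted p = 0.0252, 5 of 6). This came from the libraries with Xist, without which it was 0.68 higher (adjusted p = 0.0647). Without IR 3 alone Esr1 was not called (8.41, adjusted p = 0.0520).

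Among the 8 largest falls were Clec3a, a cartilage lectin (-3.51 ± 0.66, adjusted p = 0.000388, 6 of 6), and Chad, chondroadherin of cartilage matrix (-2.85 ± 0.54, adjusted p = 0.000419, 5 of 6). Without IR 2 these were -4.21 and -3.45. Angptl7, an angiopoietin-like matrix protein, fell too (-2.73 ± 0.42, adjusted p = 7.65e-05, 6 of 6). Ddc, the decarboxylase of aromatic amino acids, fell (-2.53 ± 0.26, adjusted p = 3.30e-06, 6 of 6), as did the cyclic nucleotide-gated channel gene Cngb3 (-2.39 ± 0.29, adjusted p = 5.99e-06, 6 of 6) and the kinase anchor gene Akap5 (-2.27 ± 0.53, adjusted p = 0.00178, 5 of 6, and -2.90 without IR 3). ATP8, a mitochondrial gene that overlaps ATP6, fell (-2.34 ± 0.71, adjusted p = 0.0135, 5 of 6). Without SHAM 1 it was -0.83 (adjusted p = 0.0744), without the libraries with Xist -2.02 (adjusted p = 0.0815), and with the replicate number as a block -1.66 (adjusted p = 0.0540). Cyp26b1, which clears retinoic acid, fell (-2.07 ± 0.67, adjusted p = 0.0179, 3 of 6). Leaving out SHAM 1 gave -1.50 (adjusted p = 0.0603), and leaving out the libraries with Xist -2.03 (adjusted p = 0.0654).

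Cardiomyocyte and energy genes fell nearly throughout their lists. Of 50 lists tested, 42 were called by fry, 29 upward and 13 downward, and camera called 0, with adjusted p = 0.290 to 0.978 with an estimated correlation. Counts of members adjusted over the list alone were the same unless given. All 18 cardiomyocyte markers fell (median log2 -0.62, adjusted p = 8.08e-05). Among them were Myl3, a ventricular myosin light chain (-1.15), the muscle creatine kinase gene Ckm (-1.22), the myoglobin gene Mb (-0.89) and Pln, a brake on the calcium pump (-0.50). All 44 nuclear genes of oxidative phosphorylation fell (median -0.70, adjusted p = 5.42e-05). These included Uqcrfs1 of complex III (-0.89), Atp5g1 of ATP synthase (-1.08), Cycs, cytochrome c (-0.80), and Ndufs4 of complex I (-0.85). Of 13 genes encoded in mitochondria 11 fell (median -0.71, adjusted p = 8.24e-05), among them COX3 (-1.07), ND1 (-0.83), ND2 (-0.71) and ATP6 (-1.22). Of 25 genes of pyruvate entry and the citric acid cycle 24 fell (median -0.66, adjusted p = 4.81e-05). The pyruvate dehydrogenase genes Pdhx (-1.03), Dlat (-0.91) and Pdhb (-1.02) and the pyruvate carrier gene Mpc2 (-0.98) led them. For each of these 4 lists camera gave adjusted p = 0.290 with an estimated correlation.

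Of 28 genes of fatty acid oxidation 22 fell and 1 rose (23 and 1 adjusted over the list alone, median -0.57, adjusted p = 0.000459, adjusted p = 0.328 with an estimated correlation). Hadh of the third beta-oxidation step fell (-0.94), as did Acsl1, which activates fatty acids (-0.78), and Etfa, which passes on electrons (-0.70). Of 20 ion channel and calcium handling genes 9 fell and 1 rose (10 and 1 adjusted over the list alone, median -0.40, adjusted p = 0.00300, adjusted p = 0.385 with an estimated correlation). Those that fell included the calcium channel subunit gene Cacna2d1 (-0.70), the potassium channel genes Kcnd2 (-0.90) and Kcnip2 (-0.82), and Casq2, which stores calcium in the sarcoplasmic reticulum (-0.70). The list of cardiac stress and fetal genes was not called (7 of 18 rose and 3 fell, 7 and 4 adjusted over the list alone, median 0.36, adjusted p = 0.138). Without IR 2 it was (adjusted p = 0.0494). Within it the stress cytokine gene Gdf15 rose (1.89) and the actin genes Actc1 (-0.81) and Acta1 (-2.04) fell. The natriuretic peptide gene Nppa rose (1.38 ± 0.51, adjusted p = 0.0365, 4 of 6). It was not called when any of 7 libraries (IR 2, 3 or 6, SHAM 1, 3, 4 or 5) was left out (adjusted p = 0.0564 to 0.108), without the libraries with Xist (1.36, adjusted p = 0.0626) or with no low-count filter (1.39, adjusted p = 0.0651). Nppb, its ventricular relative, was 0.69 ± 0.33 higher and did not pass the test, but passed without IR 2 (0.85, adjusted p = 0.0351) and on log2(FPKM + 1) and log2(FPKM + 0.1) (0.82, adjusted p = 0.0457 and 0.0472).

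Most matrix genes rose, and fibroblast markers rose on balance. Of 31 collagen and crosslinking genes 29 rose and 1 fell (median 2.11, adjusted p = 0.000131). The fibrillar collagen gene Col3a1 rose by 4.08 ± 0.53 (adjusted p = 1.91e-05, 6 of 6), the crosslinking oxidase gene Loxl1 by 1.65 and the microfibrillar collagen gene Col6a1 by 1.31. Of 26 genes of matrix proteases and their inhibitors 19 rose and 3 fell (20 and 3 adjusted over the list alone, median 1.61, adjusted p = 3.63e-05). They included the membrane collagenase gene Mmp14 (3.25), the protease inhibitor gene Timp2 (0.52) and the urokinase receptor gene Plaur (2.06). Of 19 TGF-beta genes 14 rose and 0 fell (1 adjusted over the list alone, median 0.77, adjusted p = 4.81e-05). Among them were the receptor Tgfbr2 (0.85), the ligand Tgfb1 (0.74), the latency binding protein Ltbp3 (0.77) and the induced matrix protein Tgfbi (1.84). Of 15 resident fibroblast markers 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.35, adjusted p = 4.81e-05). The growth factor receptor gene Pdgfra rose by 0.92 and the stromal antigen gene Cd248 by 1.17. For each of these 4 lists camera gave adjusted p = 0.290 with an estimated correlation. Of 18 markers of activated fibroblasts 10 rose and 2 fell (median 1.18, adjusted p = 0.00647, adjusted p = 0.444 with an estimated correlation). They included Postn, a scar matrix protein (3.52 ± 0.63, adjusted p = 0.000268, 6 of 6), the matrix glycoprotein gene Tnc (6.90) and Cthrc1, which marks scar-forming fibroblasts (7.09). The matricellular gene Ccn4 (3.87) and the Wnt antagonist gene Sfrp1 (1.99) rose as well.

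Genes of myeloid cells and of lymphocytes rose as well. Of 21 macrophage markers 19 rose (median 2.20, adjusted p = 3.63e-05). These were led by the lipid-sensing receptor gene Trem2 (3.35), the galectin gene Lgals3 (4.72) and the complement genes C1qa (1.43) and C1qc (1.45). The macrophage level per library, the mean log2(CPM + 1) of the markers, was 3.75 ± 0.138 in SHAM and 5.87 ± 0.355 in IR. Of 11 monocyte markers 10 rose (median 3.55, adjusted p = 4.88e-05), with the recruitment receptor gene Ccr2 at 3.55 and the lectin gene Chil3 at 6.93. All 10 T and NK cell markers that passed the low-count filter rose (median 2.51, adjusted p = 0.000116), and other members of the list were not tested. They included Cd3g of the T cell receptor complex (2.81), the interleukin-7 receptor gene Il7r (3.96), the kinase gene Lck (2.95) and Cd4 (1.43). Their level per library was only 0.218 ± 0.0499 in SHAM, against 0.869 ± 0.338 in IR. A filter by group can pass such markers only through the groups where they are high, so it partly sets the count of rises. Each of these 3 lists had adjusted p = 0.290 with an estimated correlation. Of 13 neutrophil markers 8 rose (9 adjusted over the list alone, median 2.59, adjusted p = 0.00120, adjusted p = 0.397 with an estimated correlation). Among them were Trem1 (4.50), Csf3r (3.03), the gelatinase gene Mmp9 (4.93) and the siderophore-binding gene Lcn2 (3.81). Of 8 markers of B and plasma cells 2 rose (1 adjusted over the list alone, median 0.69, adjusted p = 0.00297, adjusted p = 0.444 with an estimated correlation). The inhibitory receptor gene Cd22 rose by 3.06. Of 12 genes of dendritic cells and MHC class II 10 rose (median 1.38, adjusted p = 0.00401, adjusted p = 0.414 with an estimated correlation). The growth receptor gene Flt3 (3.07) and the peptide loading gene H2-DMb1 (1.63) were among them. Of 7 mast cell markers 2 rose (median 0.57, adjusted p = 0.0415, adjusted p = 0.617 with an estimated correlation). The histamine-forming Hdc rose by 1.55, and the list was not called when any of 8 libraries (IR 1 to 4, SHAM 1, 2, 4 or 5) was left out (adjusted p = 0.0572 to 0.0950).

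Signals between these cells followed. Of 25 chemokine and cytokine genes 23 rose (median 2.69, adjusted p = 4.88e-05), including Cxcl16 (2.00), the monocyte attractant Ccl8 (3.99) and the alarmin Il33 (2.30). Of 17 complement genes 16 rose (median 1.93, adjusted p = 3.63e-05), among them the integrin chain Itgb2 (2.61) and C1qb (1.67). Of 19 genes of the inflammasome and necroptosis 17 rose (18 adjusted over the list alone, median 1.32, adjusted p = 8.08e-05). The necroptosis genes Ripk3 (1.76) and Mlkl (1.40) and the adaptor gene Myd88 (1.12) were among them. Of 21 apoptosis genes 10 rose (median 0.24, adjusted p = 7.48e-05). They included the apoptosome gene Apaf1 (0.98) and Pmaip1, which triggers mitochondrial permeabilisation (3.14). Of 27 cell cycle genes 25 rose and 1 fell (26 and 1 adjusted over the list alone, median 2.49, adjusted p = 0.000131). Among them were the ubiquitin ligase gene Ube2c (2.88), the mitotic kinase gene Aurka (2.33), the cyclin gene Ccnb1 (3.87) and the replication helicase gene Mcm3 (1.05). Each of these 5 lists had adjusted p = 0.290 with an estimated correlation. Of 19 interferon response genes 16 rose (18 adjusted over the list alone, median 0.95, adjusted p = 0.00221, adjusted p = 0.385 with an estimated correlation). The transcription factor Irf7 rose by 1.65 and the nucleic acid sensor Zbp1 by 2.78.

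Endothelial and smooth muscle lists moved less. Of 17 endothelial markers 6 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.00847, adjusted p = 0.444 with an estimated correlation), with a median of -0.20 that was 0.10 with total-count scaling. Among them the water channel gene Aqp1 fell (-1.29), the complement response gene Rgcc fell (-0.75) and the clotting factor gene Vwf rose (0.69). Of 13 markers of smooth muscle and pericytes 6 fell (adjusted p = 0.0248, adjusted p = 0.460 with an estimated correlation), with a median of -0.22 that was 0.08 with total-count scaling. Among these were the adhesive glycoprotein gene Vtn (-0.65), the pericyte potassium channel gene Kcnj8 (-0.62) and the smooth muscle myosin gene Myh11 (-0.49). The list was not called without IR 2 or IR 4 (adjusted p = 0.0592 to 0.0696). Its level per library did not pass the exact permutation test (adjusted p = 0.104).

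Genes that promote ferroptosis rose on balance, and those that restrain it went both ways, in the libraries in which 19 of 21 macrophage markers rose (median 2.20). Of 25 promoting genes 12 rose and 4 fell (13 and 5 adjusted over the list alone, median 0.34, adjusted p = 0.000179, adjusted p = 0.328 with an estimated correlation). Among them were Acsl4, which builds oxidisable lipids (0.76 ± 0.17, adjusted p = 0.00114, 6 of 6), the cyclooxygenase gene Ptgs2 (2.20 ± 0.41, adjusted p = 0.000271, 6 of 6), Cybb, the NADPH oxidase of phagocytes (2.20), the spermidine acetyltransferase gene Sat1 (0.98) and the outer membrane channel gene Vdac3, which fell (-0.41). The transferrin receptor gene Tfrc was -1.16 ± 0.50 and did not pass (adjusted p = 0.0647, 5 of 6). It passed without IR 3 (-1.59, adjusted p = 0.0144) or SHAM 5 (-1.31, adjusted p = 0.0448), with DESeq2 (-1.17, adjusted p = 0.0416), with a term for the libraries with Xist (-1.53, adjusted p = 0.0205) and without those libraries (-1.49, adjusted p = 0.0315). Without SHAM 1 it was -0.51 (adjusted p = 0.303). Of 24 restraining genes 6 rose and 6 fell, and the list was not called (median 0.01, adjusted p = 0.539). Gpx4, which reduces lipid peroxides, fell from 561 ± 35.8 to 412 ± 58.5 CPM (-0.45 ± 0.11, adjusted p = 0.00253, 5 of 6), and did not pass on FPKM (-0.15, adjusted p = 0.129 to 0.135). Slc7a11, the cystine importer, rose from 0.0498 to 0.995 CPM (4.13 ± 0.88, adjusted p = 0.000738, 5 of 6, and 5.75 without SHAM 5). Its partner gene Slc3a2 rose (0.66), as did the aldo-keto reductase gene Akr1c13 (1.90), and Dhodh, which reduces ubiquinone in mitochondria, fell (-0.76).

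Heme synthesis fell and heme uptake, export and breakdown rose, in the same libraries in which all 18 cardiomyocyte markers fell (median -0.62) and 19 of 21 macrophage markers rose (median 2.20). Of 15 heme synthesis genes 11 fell and 2 rose (median -0.47, adjusted p = 4.81e-05). Those that fell included Uros (-0.67) and Cpox (-0.69) of the porphyrin steps, and the mitochondrial genes Abcb10 (-0.72) and Tmem14c (-0.39). Of 16 genes of heme uptake, export and breakdown 8 rose and 1 fell (median 0.38, adjusted p = 4.81e-05), and each of these lists had adjusted p = 0.290 with an estimated correlation. Hmox1, which opens the heme ring and frees its iron, rose from 11.2 ± 1.86 to 110 ± 79.4 CPM (3.29 ± 0.50, adjusted p = 7.47e-05, 6 of 6). The haptoglobin gene Hp rose (6.00), and so did the hemopexin receptor gene Lrp1 (0.94) and the heme exporter gene Flvcr1 (0.85). Of 22 iron genes 9 rose and 2 fell (median 0.20, adjusted p = 0.000631, adjusted p = 0.385 with an estimated correlation). The transferrin gene Trf (0.95) and the metal transporter genes Slc11a1 (2.23) and Slc39a8 (2.24) were among those that rose. The ferritin light chain gene Ftl1, which has near-identical copies, rose from 299 ± 19.0 to 772 ± 195 CPM (1.37 ± 0.16, adjusted p = 5.77e-06, 6 of 6). The heavy chain gene Fth1 was -0.04 ± 0.09 (adjusted p = 0.773), which turned to 0.27 on FPKM (adjusted p = 0.0155). Of 27 NRF2 and antioxidant genes 9 rose and 3 fell (median 0.11, adjusted p = 0.00300, adjusted p = 0.455 with an estimated correlation). These included the secreted peroxidase gene Gpx3 (1.30), the pentose phosphate genes G6pdx (1.28) and Tkt (0.95), and the mitochondrial dismutase gene Sod2, which fell (-0.76).

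**Figure D2:**
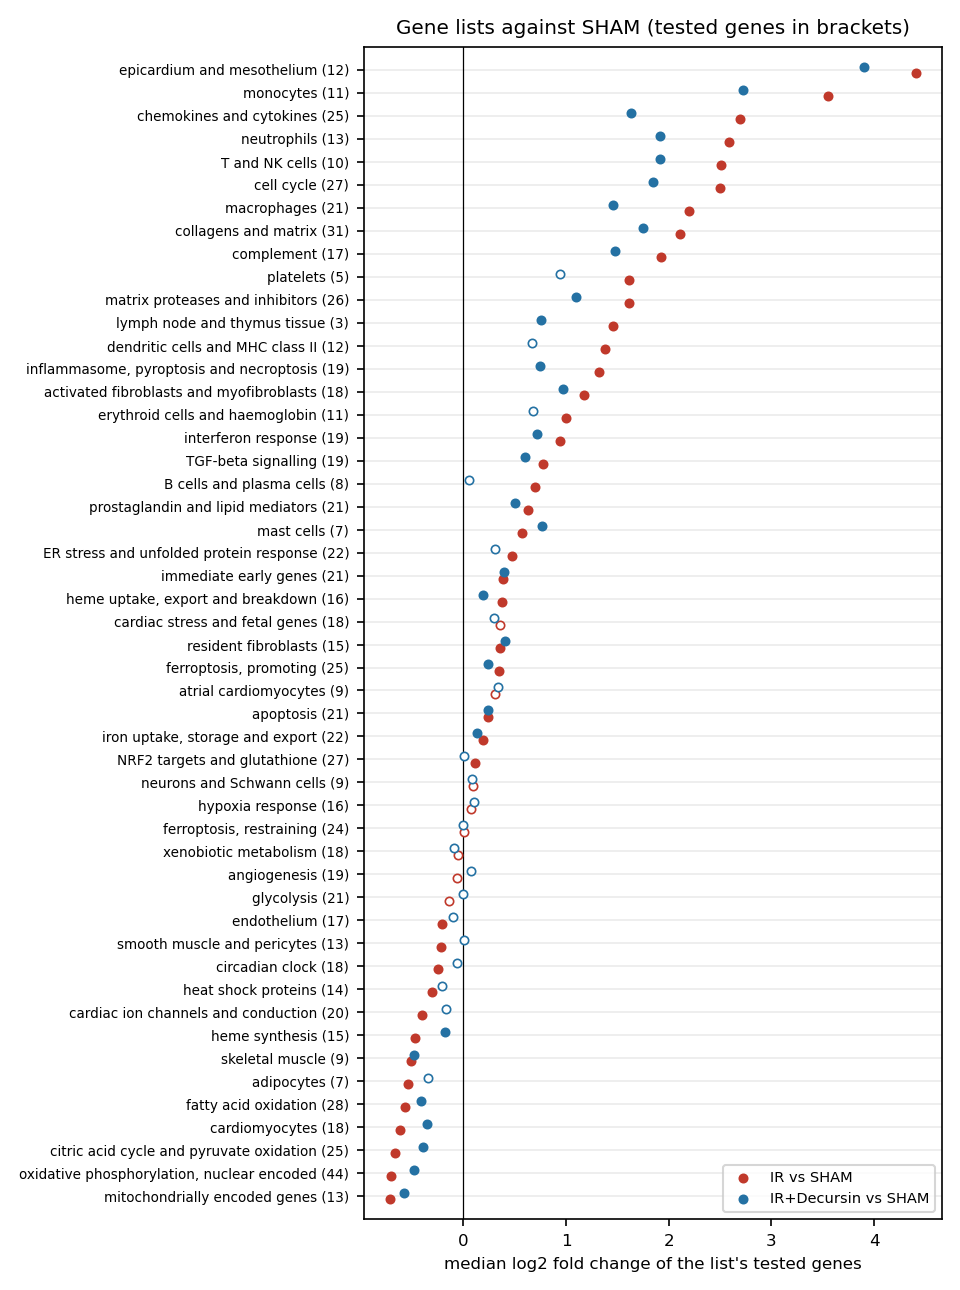
Median log2 fold change of the members of each list (tested genes in brackets) in IR and in IR+Decursin against SHAM. Points are filled where fry gave an adjusted p under 0.05 and open where not called. Matrix, immune and cell cycle lists lie right of 0 and energy lists left of 0 against SHAM.

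In IR+Decursin hearts, the fetal myosin gene Myh7, the heme oxygenase gene Hmox1, the protease inhibitor gene Timp1 and the ferritin gene Ftl1 had lower means than in IR, but no gene passed the edgeR test. Myh7 stood at 365 ± 261 CPM against 1554 ± 1189 in IR (-2.09 ± 0.52, adjusted p = 0.0981), Hmox1 at 46.7 ± 31.0 against 110 ± 79.4 (-1.24 ± 0.46, adjusted p = 0.191), Timp1 at 57.7 ± 38.6 against 116 ± 37.3 (-1.01 ± 0.47, adjusted p = 0.267) and Ftl1 at 532 ± 132 against 772 ± 195 (-0.54 ± 0.16, adjusted p = 0.129). DESeq2 called Myh7 (-2.08, adjusted p = 0.00903) and Ftl1 (-0.54, adjusted p = 0.0411), but not Hmox1 (adjusted p = 0.0892) or Timp1 (adjusted p = 0.197). Gpx4 stood at 465 ± 76.9 against 412 ± 58.5 CPM (0.18, adjusted p = 0.405) and Myh6 was 0.40 higher (adjusted p = 0.191). The edgeR test called 0 genes, with a smallest adjusted p of 0.0883 and 2712 genes at unadjusted p < 0.05 (1524 higher, 1188 lower). DESeq2 called 429 (345 higher, 84 lower), limma with voom and quality weights 0 (2257 at unadjusted p < 0.05), and limma-trend on FPKM 0 in 3 settings (2751, 2655 and 2122 at unadjusted p < 0.05). The edgeR test called 976 genes (696 higher, 280 lower) without IR+Decursin 1 and 2 without IR+Decursin 4. IR+Decursin 1 had the highest index of the IR change in its group (0.886). Without it the difference of the mean index from IR went from -0.280 to -0.343, so leaving it out moves the group away from IR. The median of all genes was -0.10 with total-count scaling.

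None of the genes with the smallest p was called by edgeR, and no common function among them was tested. For each, 6 of 6 IR+Decursin libraries lay on the given side of the IR mean. The higher ones included the uracil glycosylase gene Ung (0.64 ± 0.12), Pdss1, which makes the ubiquinone tail (0.58 ± 0.11), the mitochondrial reductase gene Rtn4ip1 (0.53 ± 0.10) and the potassium channel gene Kcnd2 (0.67 ± 0.13). The lower ones were the splicing factor gene Hnrnpa1 (-0.35 ± 0.08), the lipid droplet gene Hilpda (-0.74 ± 0.16), the lysosomal channel gene Tpcn2 (-0.73 ± 0.17), Ccdc163, of unknown function (-0.67), and the lysosomal tetraspanin gene Cd63 (-0.50). Adjusted p was 0.0883 for each except Ccdc163 and Cd63 (0.0930). DESeq2 called all 9 of these, for example Ung (0.64, adjusted p = 0.00133), Rtn4ip1 (0.53, adjusted p = 0.00228) and Hilpda (-0.74, adjusted p = 0.00535). So did edgeR without IR+Decursin 1, for example Rtn4ip1 (0.58, adjusted p = 0.00860) and Cd63 (-0.56, adjusted p = 0.0176), and it then called Hmox1 (-1.61, adjusted p = 0.0477), Ptgs2 (-1.39, adjusted p = 0.0292), Ftl1 (-0.64, adjusted p = 0.0284) and Myh7 (-2.09, adjusted p = 0.0471). With edgeR Pdss1 was also called without IR+Decursin 4 (0.65, adjusted p = 0.0310). Of the rest of the panel, Slc7a11 was -1.35 (adjusted p = 0.293), Acsl4 -0.31 (adjusted p = 0.333), Ptgs2 -0.96 (adjusted p = 0.210), and Tfrc 0.84 (adjusted p = 0.376). Fth1 was -0.03 (adjusted p = 0.892), Nppa -0.33 (adjusted p = 0.763) and Nppb -0.09 (adjusted p = 0.911). Without IR 2, Nppa was 0.04 (adjusted p = 0.975), and without IR 5, Nppb was 0.15 (adjusted p = 0.825). Among matrix genes, Col1a1 was -0.47 (adjusted p = 0.654), Col3a1 -0.47 (adjusted p = 0.621) and Postn -0.53 (adjusted p = 0.642).

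Medians of heme synthesis, the citric acid cycle and oxidative phosphorylation were above 0 against IR, and those of macrophages and chemokines below 0, but fry called 0 lists (smallest adjusted p 0.104, 18 lists at unadjusted p < 0.05). Camera called 0 too (adjusted p = 0.408 to 0.978 with an estimated correlation), and the either-direction fry test called 16. Adjusted over the list alone, 8 of 15 heme synthesis genes were higher (median 0.21, fry adjusted p = 0.104). They included the rate-setting Alas1 (0.76), Alad of the second step (0.48) and the transporters Abcb10 (0.43) and Abcb6 (0.40). In the same way 11 of 25 citric acid cycle genes were higher (median 0.27, adjusted p = 0.116), with Dlat at 0.49 and the citrate synthase gene Cs at 0.42. So were 11 of 44 nuclear genes of oxidative phosphorylation (median 0.21, adjusted p = 0.176), with the complex III genes Uqcrc1 at 0.56 and Cyc1 at 0.49. Of 18 cardiomyocyte markers 2 were higher adjusted over the list alone (Ckm 0.62 and Myl3 0.52, list adjusted p = 0.116), and of 20 ion channel genes 6 (median 0.25, adjusted p = 0.132). Of 27 NRF2 genes 5 were lower and 1 higher adjusted over the list alone (median -0.13, adjusted p = 0.116). The peroxidase genes Gpx1 (-0.43) and Gpx3 (-0.45), the thioredoxin gene Txn1 (-0.38) and the glutathione reductase gene Gsr (-0.35) were lower. The ferroptosis lists had 0 such members (promoting, median -0.08, adjusted p = 0.203, restraining, median 0.00, adjusted p = 0.735). So had macrophages (median -0.65, adjusted p = 0.116) and collagens (median -0.36, adjusted p = 0.400). The list of cardiac stress and fetal genes had a median of -0.05 (adjusted p = 0.978). Of 25 chemokine genes (median -0.76, adjusted p = 0.116) 2 were lower adjusted over the list alone, Tnf (-1.39) and the neutrophil attractant Cxcl2 (-2.78). Without IR+Decursin 1 fry called 16 lists, 8 upward, including heme synthesis (adjusted p = 0.0197), cardiomyocytes (adjusted p = 0.0343) and oxidative phosphorylation (adjusted p = 0.0409). The other 8 were downward, including macrophages (adjusted p = 0.0400), T and NK cells (adjusted p = 0.0400) and chemokines (adjusted p = 0.0343). IR+Decursin 1 had the highest index of the IR change in its group. Leaving out IR+Decursin 5 or 6, which had the lowest, changed no list call. Without IR 3 fry called the NRF2 list (adjusted p = 0.0378). Of the 25 list levels per library 0 passed the exact permutation test and 4 had an exact p under 0.05. B and plasma cells (0.582 ± 0.130 against 0.927 ± 0.331, exact p = 0.0130) and platelets (1.61 ± 0.351 against 2.19 ± 0.323, exact p = 0.0152) were lower. Heme synthesis (5.09 ± 0.138 against 4.89 ± 0.132, exact p = 0.0368) and smooth muscle and pericytes (5.96 ± 0.0837 against 5.74 ± 0.227, exact p = 0.0476) were higher.

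**Figure D3:**
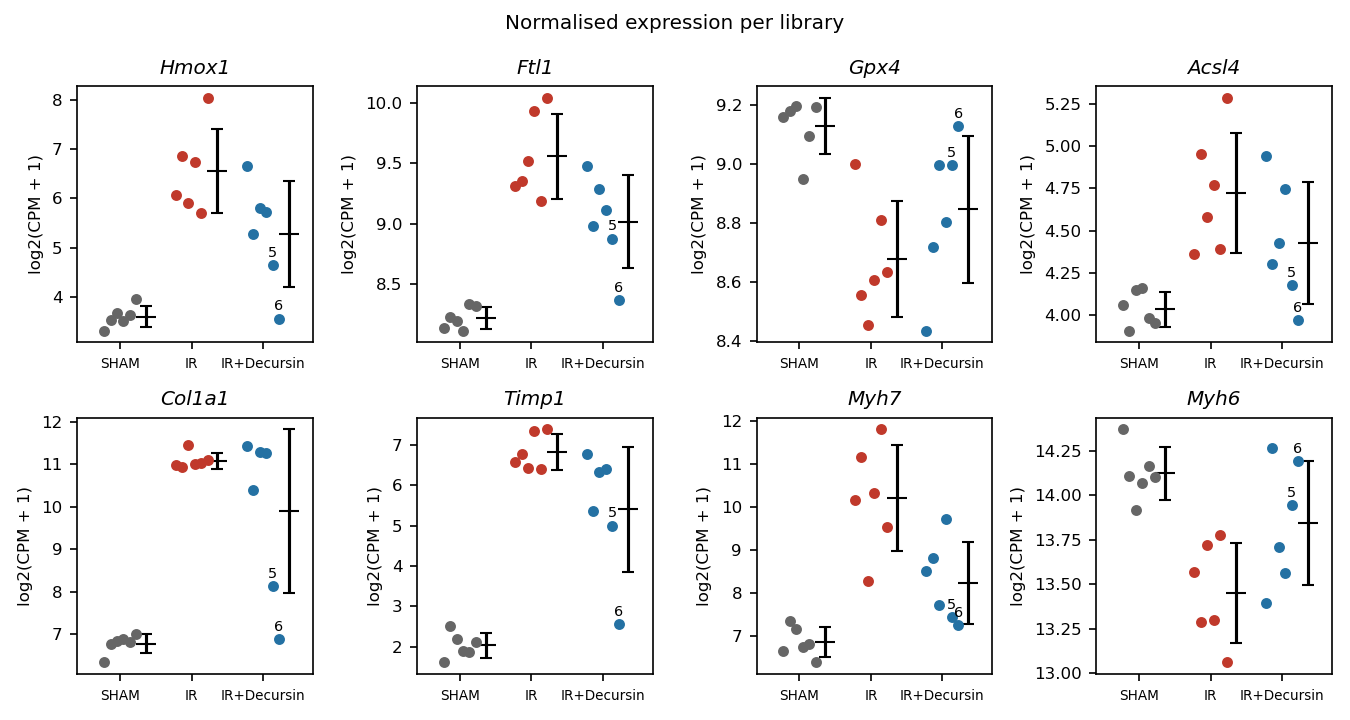
CPM of named cardiac, matrix, heme and ferroptosis genes per library (log scale), by group, with bars for mean ± SD over 6 animals. Hmox1, Ftl1, Timp1 and Myh7 have their highest means in IR.

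The index of the IR change differed between IR+Decursin animals. On this index, with a mean of 0 for SHAM, IR libraries stood at 0.850 ± 0.113 (0.719 to 0.994) and IR+Decursin libraries at 0.570 ± 0.291, so that 67.0% remained (difference -0.28, two-sided exact permutation p = 0.0411). The test exchanged finished index values. IR libraries helped to choose the genes and were scored in 1 part each. IR+Decursin libraries chose no genes and were averaged over both parts, so the p is approximate. The IR+Decursin libraries 1 to 6 stood at 0.886, 0.607, 0.702, 0.771, 0.345 and 0.107. With the finished index value of a single library left out, 59.6% (without IR+Decursin 1, exact p = 0.0108) to 77.9% (without IR+Decursin 6, exact p = 0.0736) remained. Genes and scaling were not chosen anew, so a left-out IR library still shaped the other values. The exact p exceeded 0.05 as well without IR 2, 3, 4 or 6 (0.0779, 0.0693, 0.0996, 0.0952) or IR+Decursin 2 or 5 (0.0563, 0.0671). With 67.6% and 68.9% remaining, it was 0.0649 with odd against even replicate numbers and 0.238 without the libraries with Xist. No gene was called in opposite directions by IR and by IR+Decursin against IR with edgeR, 417 were with DESeq2, and 932 with edgeR without IR+Decursin 1 (2 without IR+Decursin 4). At unadjusted p < 0.05 in both, 980 genes were up in IR and lower in IR+Decursin (337 for independent lists) and 1346 the reverse (386), of 2330 genes in all. These comparisons share the IR libraries, which alone draws their changes apart: the covariance was -0.267 against -0.0347 in simulations with IR+Decursin equal to IR (difference -0.232). Genes varied independently in these simulations, so they lack differences between animals that move many genes together. The difference from them therefore does not measure a decursin effect. Of 924 splits of the IR and IR+Decursin libraries 20 had a covariance as far below 0 (one-sided share 0.0216), the lowest at -0.353. The correlation of -0.82 was -0.69 and -0.68 when each comparison had its own IR libraries and -0.15 in these simulations, but -0.49 in simulations with no effect in any group (covariance -0.0322).

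**Figure D4:**
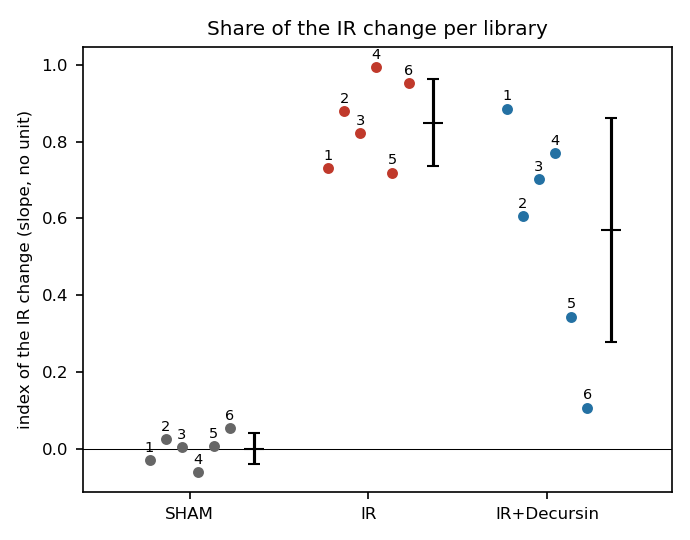
Index of the IR change per library (0 near SHAM, no unit) by group, with bars for mean ± SD over 6 animals. IR+Decursin libraries run from near SHAM to the level of IR.

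Against SHAM, scar, immune and cell cycle genes were higher and energy genes lower in IR+Decursin hearts, but not in every animal. In IR+Decursin 6 the levels of monocytes (2.23, SHAM 2.01 to 2.32) and of activated fibroblasts (3.51, SHAM 3.28 to 3.73) lay within the SHAM range. Col1a1 rose to 1575 ± 1174 CPM (3.84 ± 0.58, adjusted p = 0.000447), Col3a1 by 3.61 (adjusted p = 0.000357), Postn by 2.99 (adjusted p = 0.00235) and Timp1 by 4.19 ± 0.55 (adjusted p = 0.000253). Timp1 lay above every SHAM library in 6 of 6, and Col1a1, Col3a1, Postn, Saa3, Arg1 and Cemip in 5 of 6. Among genes that met the naming rule with its minimum of 2 CPM, Saa3, Arg1 and Cemip rose most after Esr1. The acute-phase gene Saa3 rose by 8.20 ± 1.75 (adjusted p = 0.00311) and the arginase gene Arg1 by 7.77 ± 1.53 (adjusted p = 0.00205). The hyaluronan-degrading Cemip rose by 6.89 ± 1.41 (adjusted p = 0.00229). Saa3 was 8.83 without SHAM 3 and 7.57 without IR+Decursin 4, and Cemip 6.15 without IR+Decursin 1. With voom and quality weights Saa3 (7.87, adjusted p = 0.282) and Arg1 (7.21, adjusted p = 0.130) were not called, nor was Cemip on log2(FPKM + 1) (0.43, adjusted p = 0.0883). Esr1 rose by 10.75 ± 3.55 (adjusted p = 0.0331), was 0.52 without IR+Decursin 2 (adjusted p = 0.898), and did not pass when any SHAM library was left out. Il6 had 233 counts, a ratio to SHAM of 222 (95% interval 39.5 to 8818) that was 142 without IR+Decursin 1, and Serpinb2 stood at least 91.4-fold above its floor. Falls were seen for ATP8 (-2.86 ± 0.73, adjusted p = 0.00924, but -1.34 without SHAM 1, adjusted p = 0.0155), Ddc (-1.94 ± 0.26, adjusted p = 0.000168), the transcript LOC115487369 of unknown function (-1.85 ± 0.66, adjusted p = 0.0444) and the kinase gene Map3k15 (-1.69 ± 0.59, adjusted p = 0.0405). LOC115487369 was not called when any of 9 libraries (IR+Decursin 1 to 4 or 6, SHAM 1 to 4) was left out (adjusted p = 0.0517 to 0.0992), nor Map3k15 for any of 8 (IR+Decursin 1, 2, 3, 5 or 6, SHAM 1, 3 or 4, adjusted p = 0.0701 to 0.0816). With no low-count filter neither LOC115487369 (-1.84, adjusted p = 0.0985) nor Map3k15 (-1.69, adjusted p = 0.0794) was called, nor on log2(FPKM + 1) (-0.91, adjusted p = 0.0650, and -0.85, adjusted p = 0.0520). In all 2647 genes rose and 1774 fell (29.3% changed, 59.9% upward), 1138 and 76 of them at least 2-fold. The median of all genes was 0.22 with total-count scaling. Limma-trend on FPKM gave 3936 up and 395 down with a median of 0.12 (4268 and 387 with 0.19, 3420 and 362 with 0.15). Leaving out 1 library gave 3461 (without IR+Decursin 1) to 5130 genes (without IR+Decursin 6).

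Of the ferroptosis, iron and heart panel, Hmox1 (2.05 ± 0.48, adjusted p = 0.00529), Ftl1 (0.83 ± 0.16, adjusted p = 0.00121), Slc7a11 (2.78 ± 0.91, adjusted p = 0.0273), Ptgs2 (1.24 ± 0.41, adjusted p = 0.0288) and Myh7 (1.62 ± 0.51, adjusted p = 0.0263) rose. Slc7a11 was not called when any of 7 libraries (IR+Decursin 1 or 4, SHAM 1, 2, 3, 4 or 6) was left out (adjusted p = 0.0524 to 0.0633), and was 4.40 without SHAM 5. On log2(FPKM + 1) neither Slc7a11 (0.05, adjusted p = 0.371) nor Ptgs2 (0.42, adjusted p = 0.123) was called, and with no low-count filter neither Ptgs2 (1.24, adjusted p = 0.0603) nor Myh7 (1.63, adjusted p = 0.0514) was. Ptgs2 was not called without IR+Decursin 1, SHAM 1, SHAM 4 or SHAM 5 (adjusted p = 0.0522 to 0.104), nor Myh7 without IR+Decursin 4, SHAM 1 or SHAM 6 (adjusted p = 0.0526 to 0.0824). Acsl4 (0.45, adjusted p = 0.0501), Gpx4 (-0.27, adjusted p = 0.0727), Tfrc (-0.33, adjusted p = 0.657), Fth1 (-0.07, adjusted p = 0.631), Nppa (1.05, adjusted p = 0.133), Nppb (0.60, adjusted p = 0.190) and Myh6 (-0.25, adjusted p = 0.233) did not pass. Tfrc was 0.33 without SHAM 1 (adjusted p = 0.573). Without IR+Decursin 6, Acsl4 (adjusted p = 0.0157) and Gpx4 (-0.33, adjusted p = 0.0256) passed, and Acsl4 did without IR+Decursin 5 (adjusted p = 0.0371). Acsl4 also passed with DESeq2 (0.45, adjusted p = 0.0406), and both did with voom and quality weights (0.45, adjusted p = 0.0224, and -0.27, adjusted p = 0.0396).

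Fry called 30 lists against SHAM, 23 upward and 7 downward, and camera 0 (adjusted p = 0.263 to 0.983 with an estimated correlation). Of 44 nuclear genes of oxidative phosphorylation 43 fell (44 adjusted over the list alone, median -0.48, adjusted p = 0.00238, adjusted p = 0.346 with an estimated correlation), and of 13 genes encoded in mitochondria 11 (median -0.58, adjusted p = 0.000514, adjusted p = 0.263 with an estimated correlation). Of 25 citric acid cycle genes 18 fell (21 adjusted over the list alone, median -0.39, adjusted p = 0.00343, adjusted p = 0.346 with an estimated correlation), and of 28 genes of fatty acid oxidation 18 (21 adjusted over the list alone, median -0.41, adjusted p = 0.00439, adjusted p = 0.346 with an estimated correlation). Ndufa5 of complex I (-0.67), the succinate ligase gene Sucla2 (-0.63) and Hadh (-0.63) were among them. Of 18 cardiomyocyte markers 9 fell (11 adjusted over the list alone, median -0.36, adjusted p = 0.00543, adjusted p = 0.352 with an estimated correlation). Of 15 heme synthesis genes 6 fell, with Uros at -0.40 and Cpox at -0.41 (adjusted p = 0.0126, adjusted p = 0.352 with an estimated correlation), for a median of -0.18 that was 0.03 with total-count scaling. The heme synthesis level per library did not pass the exact permutation test (adjusted p = 0.111). Upward were collagens (27 of 31, median 1.75, adjusted p = 0.00283, adjusted p = 0.315 with an estimated correlation) and macrophages (19 of 21, median 1.46, adjusted p = 0.000921, adjusted p = 0.263 with an estimated correlation) with Trem2 at 2.55. So were monocytes (8 of 11, median 2.73, adjusted p = 0.00239, adjusted p = 0.315 with an estimated correlation) with Ccr2 at 2.73 and complement (15 of 17, median 1.48, adjusted p = 0.000514, adjusted p = 0.263 with an estimated correlation). Cell cycle genes rose too (25 of 27, median 1.84, adjusted p = 0.00343, adjusted p = 0.346 with an estimated correlation) with Ube2c at 2.23. Adjusted over the list alone these were 29, 20, 11, 16 and 25.

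Ferroptosis-promoting genes rose on balance (10 up and 1 down of 25, 11 and 3 adjusted over the list alone, median 0.24, adjusted p = 0.00439). So did heme uptake, export and breakdown (3 of 16 up, median 0.19, adjusted p = 0.00283) with Hp at 5.23 and Lrp1 at 0.67, and iron genes (7 up and 1 down of 22, median 0.13, adjusted p = 0.00398) with Trf at 0.74. Each of these 3 lists had adjusted p = 0.352 with an estimated correlation. The restraining list (5 up and 3 down of 24, adjusted p = 0.210) and the NRF2 list (7 up and 3 down of 27, adjusted p = 0.196) were not called. The neutrophil list was called (6 of 13 up, median 1.92, adjusted p = 0.0361, adjusted p = 0.512 with an estimated correlation) but not when any of 7 libraries (IR+Decursin 1, 3 or 4, SHAM 1, 3, 4 or 6) was left out (adjusted p = 0.0720 to 0.0862). So was the mast cell list (2 of 7 up, median 0.76, adjusted p = 0.0419, adjusted p = 0.546 with an estimated correlation) but not when any of 8 (IR+Decursin 1 to 4, SHAM 1, 2, 4 or 5) was left out (adjusted p = 0.0548 to 0.106). The levels per library of neutrophils (adjusted p = 0.105) and mast cells (adjusted p = 0.0902) did not pass the exact permutation test. Genes of dendritic cells and MHC class II were not called (1 of 12 up, adjusted p = 0.0672) except without IR+Decursin 5 or SHAM 3 (adjusted p = 0.0239 to 0.0439). Of the genes changed by IR, 2514 rose and 1563 fell in both comparisons with SHAM (668 and 384 for independent lists), and 0 in opposite directions. These comparisons share the SHAM libraries: the covariance was 0.526 against 0.0349 in simulations with no effect (difference 0.491). Genes varied independently in these simulations too. In all, 86.3% of genes had the same sign (82.2% and 79.0% with SHAM split, 67.1% simulated). A further 1296 rises and 1706 falls passed the threshold for IR and not for IR+Decursin, and 133 and 211 the other way, but these are no test of a difference between IR+Decursin and IR, for which edgeR called 0 genes (2712 at unadjusted p < 0.05), limma 0 and DESeq2 429.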

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

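The term for libraries with Xist, the tests of IR+Decursin 5 and 6 and all values named for them below were chosen only after the results were seen, and the rule for values far from their group was fixed before. Of 212 groups of values tested with that rule, 12 were past it, where about 1 in 20 would be by chance.

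IR 3, IR 4 and IR+Decursin 2 carried 14232, 14072 and 14219 counts of Xist (at most 3 in SHAM), and Esr1 was far higher in them, which in IR+Decursin 2 stood at 7382 CPM against 0.721 to 1.41 in the other libraries of its group (ratio of gap to range 0.960). The labels give all animals as male and wild type, but the highest Ddx3y count in these libraries was 0. By the term for these libraries, the Y-linked genes Kdm5d (-12.20), Uty (-10.88) and Eif2s3y (-13.86) were lower as well. The X-linked genes Kdm6a (0.89), Eif2s3x (0.72) and Kdm5c (0.76) were higher. These values argue against the male label for these hearts and go with female animals, and SHAM had no such library. A transgene carrying part of Esr1, such as a tamoxifen-inducible Cre, may account for the Esr1 reads (log2 11.90 by the same term). Cells of another tissue rich in Esr1 would be likely to bring other genes, and 0 other autosomal genes were raised at least 16-fold, which argues against it. Autosomal genes at least 16-fold lower in these libraries were Gm15446 (-6.97), LOC115490200 (-5.45), Gm31114 (-4.77) and Ifi208 (-4.28), with C7 at -3.20, and since sex, the Esr1 reads and any difference of strain fall on the same 3 libraries, no value here parts them. These libraries were not the source of the IR calls, of which 87.1% (6169 genes) remained in the same direction with the term.

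IR+Decursin 5 and 6 lay nearer SHAM (index 0.345 and 0.107) than the other IR+Decursin libraries, which weighed on the share of the IR change that remained (77.9% without IR+Decursin 6, which also held 2332306 counts of Gm26917 and a TMM factor of 0.831, beside 0.840 to 0.921 in SHAM). An exchange with a SHAM library may be set aside unless the exchanged heart itself lay near SHAM, as the highest SHAM index was 0.0540, and exchanging any of IR+Decursin 1 to 4 with any SHAM library raised it to at least 0.575 (0.319 for IR+Decursin 5, 0.0884 for 6). Atrial tissue could not account for IR+Decursin 5, whose atrial marker level was 3.05 against a highest SHAM level of 4.21, but it stays open for IR+Decursin 6 (5.32), since the only other library with such a level, IR 2 (5.35), had an index of 0.879. A small infarct, or a SHAM heart under this label, might also give the index of 0.107, and infarct size per animal would tell. A decursin effect that differs between animals is likewise possible, but an effect of the same size in all stays open as well (SD 0.291 against 0.113 in IR, two-sided exact permutation p = 0.136).

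The other values far from their group are given as ratio of gap to range, with no cause tested. Cd5l was 40.5 CPM in IR 2 against 2.91 to 7.81 in the other IR libraries (0.656). Il6 had its only SHAM count in SHAM 2 (ratio 1). Clec3a was 4.90 CPM in SHAM 1 against 13.2 to 21.4 (0.659) and Chad 4.16 against 12.0 to 20.1 (0.655). ATP8 was 329 CPM in SHAM 1 against 22.0 to 33.5 (0.849), which carried its call in IR against SHAM. Slc7a11 was 0.228 CPM in SHAM 5 against at most 0.0365 (0.825). Tfrc was 318 CPM in SHAM 1 against 51.5 to 89.4 (0.699). Col1a1 was 80.4 CPM in SHAM 1 against 108 to 128 (0.634), and 2800 CPM in IR 3 against 1965 to 2176 (0.713). Pdss1 was 10.8 CPM in IR+Decursin 4 against 14.0 to 16.3 (0.635). The level of T and NK cells was 0.916 in IR+Decursin 1 against 0.390 to 0.526 (0.742).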

How the results depend on the processing

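Camera, which compares a list with the other genes, called 0 lists for IR against SHAM (42 by fry) and 0 for IR+Decursin against SHAM (30 by fry). The lists called by fry moved on balance in one direction. Camera allows for the correlation it estimates between the genes of a list, which weakens the test where they vary together between animals. A list that it did not call is therefore not shown to move as the other genes do. For IR+Decursin against IR, DESeq2 called 429 genes where edgeR called 0, and leaving out 1 library gave 0 to 976 genes (976 without IR+Decursin 1, 2 without IR+Decursin 4). The either-direction test called 16 lists, and leaving out 1 library gave 0 to 16 (16 without IR+Decursin 1, 1 without IR 3). Genes called in opposite directions by IR and by IR+Decursin against IR numbered 0 with edgeR, 417 with DESeq2, 1 and 0 with the IR libraries divided between the comparisons in either way, and 0 to 932 with 1 library left out (932 without IR+Decursin 1, 2 without IR+Decursin 4). With the IR libraries divided, IR+Decursin against IR called only 1 and 0 genes in all. The counts of 1 and 0 could therefore not have been higher and decide nothing about opposite changes. The share of the IR change that remained, 67.0%, was 67.6% with odd against even replicate numbers (exact p = 0.0649). It was 68.9% without the libraries with Xist (exact p = 0.238). With the finished index value of 1 library left out, and genes and scaling kept, it was 59.6% to 77.9%. For each of these changed results the cause was not tested. Fth1 in IR against SHAM turned from -0.04 to 0.27 with limma-trend on FPKM at each pseudocount and filter. FPKM carry no factor that corrects for the higher share of mitochondrial counts in SHAM. Total-count scaling, which FPKM share, moved the median of all genes from -0.00 to 0.31, so the turn of Fth1 went with a shift of all genes. No cause particular to Fth1 was tested. Over all settings, leaving out 1 library gave 6599 to 7130 genes and 39 to 42 lists for IR against SHAM, and 3461 to 5130 genes and 28 to 33 lists for IR+Decursin against SHAM. With the replicate number as a block 6715, 0 and 3873 genes and 42, 0 and 31 lists were called for IR against SHAM, IR+Decursin against IR and IR+Decursin against SHAM, and libraries of the same number did not pair (correlations -0.52 to 0.41, 3 of 18 over 0.1). DESeq2 called 7571 genes for IR against SHAM and 4859 for IR+Decursin against SHAM, a term for the libraries with Xist 6354 and 4073, and leaving those libraries out 5777 and 3706. Without the libraries rich in Gm26917 these were 7221 and 5235. The directional list test was repeated only with RLE factors, the 1 CPM filter, the replicate block, each library left out, and the Xist and Gm26917 settings. In all of these in which a list kept enough genes, 37 of the 42 lists for IR against SHAM were called. For IR+Decursin against SHAM 28 of the 30 were. The exact permutation test of the 25 list levels called 20 for IR against SHAM and 12 for IR+Decursin against SHAM. It did not call smooth muscle and pericytes or erythroid cells for IR, which fry called. Nor did it call heme synthesis, neutrophils or mast cells for IR+Decursin against SHAM, which fry called too. The other scalings, voom and FPKM were not run on list tests, and total-count scaling turned the sign of some list medians. Esr1 was not called in 8 of 27 settings for IR against SHAM and in 15 of 27 for IR+Decursin against SHAM. The group equals the batch, and no setting can part them.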

Other observations

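The remaining lists concern tissue at the edges of the myocardium and the vessels. Of 12 markers of epicardium and mesothelium 11 rose in IR (median 4.40, adjusted p = 0.000944, adjusted p = 0.361 with an estimated correlation). They included the mesothelial Msln (5.70), the secreted Dmkn (6.07), Efemp1 of elastic fibres (1.44) and C3 (2.11). Of the 12, 10 rose in IR+Decursin against SHAM (12 adjusted over the list alone, median 3.90, adjusted p = 0.00335, adjusted p = 0.346 with an estimated correlation). Of 7 adipocyte markers 2 fell in IR (median -0.54, adjusted p = 0.00749, adjusted p = 0.397 with an estimated correlation), the lipid droplet gene Cidec (-2.21) and the carbonic anhydrase gene Car3 (-1.29). Of 9 skeletal muscle markers 4 fell and 1 rose in IR (median -0.51, adjusted p = 0.000253, adjusted p = 0.290 with an estimated correlation). The muscle enolase gene Eno3 fell (-1.32), while the fast troponin gene Tnnt3 rose (2.39). In IR+Decursin against SHAM 2 fell (median -0.48, adjusted p = 0.0158, adjusted p = 0.352 with an estimated correlation). Of 5 platelet markers 3 rose and 1 fell in IR (4 and 1 adjusted over the list alone, median 1.62, adjusted p = 0.00166, adjusted p = 0.385 with an estimated correlation). They were the chemokines Pf4 (1.62) and Ppbp (2.91), the integrin gene Itga2b (2.19) and Gp1ba, which fell (-1.39). Of 11 erythroid genes 6 rose (9 and 1 down adjusted over the list alone, adjusted p = 0.0476, adjusted p = 0.608 with an estimated correlation). These included the anion exchanger gene Slc4a1 (2.73), and the list was not called when any of 8 libraries (IR 1, 3 or 5, SHAM 2 to 6) was left out (adjusted p = 0.0597 to 0.108). The erythroid level per library did not pass the exact permutation test (adjusted p = 0.0593). Of 3 lymph node and thymus markers 2 rose (3 adjusted over the list alone, median 1.45, adjusted p = 0.000540, adjusted p = 0.328 with an estimated correlation), the B cell attractant Cxcl13 (6.33) and the dendritic cell attractant Ccl21a (1.05). The atrial list (median 0.31, adjusted p = 0.720) and the list of neurons and Schwann cells (median 0.10, adjusted p = 0.125) were not called, though the myelin gene Mbp rose (1.70) and the neuron list passed without IR 6 (adjusted p = 0.0439).

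Stress and signalling lists also moved in IR. Of 21 genes of prostaglandins and lipid mediators 11 rose and 4 fell (median 0.63, adjusted p = 0.000116, adjusted p = 0.290 with an estimated correlation). Among them were the leukotriene activator Alox5ap (1.82), Cyp4f18, which clears leukotrienes (3.28), and Ptges2, which fell (-0.84). Of 22 genes of endoplasmic reticulum stress 12 rose and 1 fell (13 and 2 adjusted over the list alone, median 0.47, adjusted p = 0.00330, adjusted p = 0.444 with an estimated correlation). The asparagine synthetase gene Asns rose by 1.47 and the chaperone gene Pdia4 by 1.15. Of 21 immediate early genes 11 rose (13 adjusted over the list alone, median 0.39, adjusted p = 0.000631, adjusted p = 0.379 with an estimated correlation). They included the transcription factors Myc (2.06), Junb (1.60) and Egr2 (2.35). Of 14 heat shock genes 6 fell (median -0.31, adjusted p = 0.0248, adjusted p = 0.460 with an estimated correlation). Those were led by the mitochondrial chaperones Hspd1 (-0.69) and Hspe1 (-0.75), and the list was not called without IR 2, SHAM 2 or SHAM 5 (adjusted p = 0.0545 to 0.128). Of 18 circadian clock genes 3 fell and 1 rose (adjusted p = 0.0397, adjusted p = 0.455 with an estimated correlation), with the output factors Hlf (-0.84) and Tef (-0.55) among them, a median of -0.25 that was 0.05 with total-count scaling, and no call when any of 6 libraries (IR 4 or 6, SHAM 1, 3, 4 or 6) was left out (adjusted p = 0.0620 to 0.0936).

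Glycolysis genes went both ways in IR (5 up and 10 down of 21, adjusted p = 0.0589, median -0.14, and 0.18 with total-count scaling). The glucose transporter gene Slc2a1 (0.86) and the lactate exporter gene Slc16a3 (3.61) rose and the muscle mutase gene Pgam2 (-1.04) fell. The list passed without IR 1, IR 5 or SHAM 3 (adjusted p = 0.0239 to 0.0401). The hypoxia list (6 up and 4 down of 16, median 0.08, adjusted p = 0.298) was not called, and within it Hif1a rose (0.67) and the mitochondrial Higd1a fell (-0.98). The angiogenesis list was not called either (4 up and 3 down of 19, adjusted p = 0.291, median -0.06, and 0.24 with total-count scaling), with the growth factor gene Hgf (2.73) and the chemokine receptor gene Cxcr4 (1.66) up and Vegfb down (-0.65). Nor was xenobiotic metabolism (5 up and 4 down of 18, adjusted p = 0.0589, median -0.05, and 0.26 with total-count scaling), in which the retinoic acid-forming Aldh1a2 (2.51) and Cyp1b1 (2.06) rose, and which passed without IR 3 (adjusted p = 0.00640).

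The tests in this paragraph were chosen only after the results were seen. Cardiomyocyte and mitochondrial lists were lower and immune and matrix lists higher in IR than in SHAM. A lower share of cardiomyocytes alone may be set aside, as it would raise all other cells alike and the macrophage level rose 2.37 more than the endothelium level. A few genes taking most of the counts could not give all of it, since they would shift all other genes alike, and the levels of macrophages and collagens moved 2.78 ± 0.21 SE (log2) apart from those of cardiomyocytes and oxidative phosphorylation. Loss of these transcripts in step with all cardiomyocyte transcripts stays a candidate explanation (oxidative phosphorylation minus cardiomyocyte level -0.0433, SE 0.06, two-sided exact permutation p = 0.487), which counts of nuclei or stained sections would test. Batch might add to any of it, as 0 batch labels hold more than 1 group.

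Counts in 100 splits of the 12 libraries of a comparison, the real one included, were planned before the data were examined, and the splits for the covariance were not planned. For IR against SHAM 1 split had as many genes as the real one (7079, highest other 2605) and 1 as many lists (42, highest other 34), which excluded chance. For IR+Decursin against SHAM 1 split had as many genes (4421, highest other 1379) and 1 as many lists (30, highest other 21), which excluded it as well. For IR+Decursin against IR the real counts of genes and lists were 0, which all 100 splits reach whatever the data, so these counts decide nothing. The split with 407 genes exchanged 2 libraries of each group and the split with 17 lists exchanged 1, so both kept most of the real grouping. Structure within the groups was not tested. Of the 100 splits 6 had as many genes at unadjusted p < 0.05 (2712, highest other 4320), so chance was not excluded for that count. Over all 924 splits, 20 had a covariance of the IR change with the IR+Decursin difference as far below 0 as the real -0.267 (share 0.0216, lowest -0.353). That count was one-sided in the direction already seen, no library was left out of it, and it does not settle whether chance is excluded.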
